A study of Mus musculus with 2 samples.

How the data were processed

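T cells from mouse hearts 7 days after myocardial infarction were profiled with a droplet-based 3′ single-cell RNA kit, per the labels' protocols, in 1 library from anti-IgG and 1 from anti-PD1 injected mice. The first bases of the barcodes resemble those of another kit version, and no barcode list was used here to check it. The kit is therefore given as labelled, and which end of the transcripts was read bears on how receptor segments such as Trdv4 and Trgv6 were counted. The deposited values are raw UMI counts per gene and barcode, with no normalization. Per the file headers, the counts were written by Cell Ranger 7.1.0, while the submitters' processing notes name Cell Ranger 7.2.0, Seurat 4.4.0 and the build mm10. The annotation behind the gene IDs is not given in the sources used here; 52081 of the IDs were found in the GENCODE reference table, which was used only to match gene names, and no coordinates are given. The deposited barcodes were already limited to called cells. The series design speaks of sorted T cells and the labels' protocols describe digestion, red cell lysis and dead cell removal but no sort.

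Cells with at least 300 genes and 500 UMIs and at most 10% mitochondrial UMIs were kept (4309 of 4380 anti-IgG and 5835 of 6026 anti-PD1 barcodes). Scrublet in scanpy 1.11.5 was run per library. Its automatic threshold marked 0 cells in both libraries, so, as a choice made after that was seen, the highest-scoring cells were removed at the expected rate of 0.8% per 1000 cells (149 and 272 cells). UMIs were scaled per cell and log transformed, 2000 variable genes were chosen without mitochondrial, ribosomal (including ribosomal RNA), haemoglobin, immunoglobulin, T cell receptor segment, Xist and Y-linked genes, and 30 principal components (scikit-learn 1.9.0) were used for a shared-neighbour graph of 15 neighbours. Clusters came from leidenalg 0.10.2 at resolution 1, with both libraries together and no integration. Numerical work used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15, and figures matplotlib 3.10.9.

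Clusters were named from 24 sets of marker genes fixed before the data were examined. The naming rule was written after a first clustering, with its cells per library, had been seen. A cluster took a non-T name when at least 3 markers were in at least 20% of its cells at a log2 fold of at least 1 against the other cells, and counted as mixed when at least 75% of its cells also had a Cd3 UMI. A cluster with Cd3 UMIs in at least 75% of cells took the T class with the highest mean log2 fold among classes with at least 3 markers in at least 10% of cells at a fold of at least 1.5. Naive clusters were called CD4 or CD8 by which of Cd4 and Cd8a was seen in more of their cells. A cluster stayed unnamed when another class had more markers among its top 10 genes or its own class had 0; the last condition was added after cluster 19 had been seen. The macrophage-like class was left out of the comparisons within classes after its values had been seen, because 57.2% of its cells had a Cd3 UMI.

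UMIs were summed over the cells of a library and divided by their total, and the anti-PD1 over anti-IgG ratio was given with an exact 95% interval conditional on the summed UMIs. Shares of cells have exact Clopper-Pearson 95% intervals. All intervals cover counting error only, and cells were not treated as replicates. Intervals of gene ratios treat each UMI as drawn singly, so they are too narrow where UMIs lie together in few cells. In B-like cells, for example, 33 anti-IgG UMIs of Lyz2 came from 1 cell. A gene with 0 UMIs in a library was set to a floor of 3 counts for ranking and list medians. The 28 gene lists were fixed before the data were examined: checkpoint and exhaustion, cytotoxic effector, Th1, Th2, Th17 and gamma-delta 17 and Treg programs, naive and memory, early activation and AP-1, type I interferon, interferon gamma and GTPases, cell cycle, chemokine receptors and homing, tissue residency, cytokines and tissue repair, costimulation and TNF receptors, TCR complex and signalling, glycolysis, oxidative phosphorylation, lipid metabolism, apoptosis and survival, TGF-beta response, heat shock and dissociation, unfolded protein response, NK receptors and free RNA of heart muscle, stroma and vessel, myeloid and red cells. Of their 547 symbols, 544 matched by symbol and 3 through the gene ID, and some genes stand in more than 1 list. For members with at least 50 summed UMIs, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins; the percentile describes these libraries and is not a test of the treatment.

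Named genes followed a rule fixed before the data were examined. In all T-lineage cells they were the 12 highest and 12 lowest ratios among genes with at least 100 summed UMIs, a ratio of at least 1.5 either way and an interval that excluded 1. In each T class with at least 100 cells per library, without clusters holding markers of 2 lineages, they were the 5 highest and 5 lowest by the same limits. For each list they were up to 4 members with the largest log2 ratio in size, and 21 genes were always named: Pdcd1, Cd274, Ctla4, Lag3, Havcr2, Tigit, Tox, Tcf7, Foxp3, Ifng, Tnf, Gzmb, Prf1, Gzmk, Il17a, Il10, Tgfb1, Areg, Cd4, Cd8a and Mki67. Not every gene that this rule names is reported here. The highest and lowest genes leave out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor segment, Gm-number, Rik, Xist and Y-linked genes. The pattern for Rik models was widened after a first ranking had been seen, and genes higher or lower in every class were collected after the values within classes had been seen.

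The ratio and list steps were tested on simulated data made from the real gene means and library totals, with 200 genes changed; 12046 genes entered the ratio step. Of unchanged genes 95.6% of intervals held the true ratio and 0.194% passed the size limits, while 100% of genes changed to 2 times and 57.6% of those changed to 1.5 times passed them. The counts were drawn as Poisson sums per library, the model that the intervals assume, so this checks the calculation only. Single cells did not enter the simulation. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs without replacement. Alternatives fixed before the data were examined kept doublets, required 1000 genes per cell or at most 5% mitochondrial UMIs, left out T-lineage cells with 2 or more macrophage-marker UMIs, took classes from marker UMIs per cell, changed the resolution to 0.5 or 1.5, centred genes within each library, used 1000 variable genes, scaled by the median ratio or to totals without mitochondrial, ribosomal protein and haemoglobin genes and Malat1, weighted each cell alike, thinned cells to 1000 UMIs (2000 for shares of cells), set the same class mix, and took list members with at least 10 or 200 UMIs. Alternatives chosen after seeing the data took gamma-delta cells by Trdv4 or Trgv6 UMIs, scaled without the ribosomal RNA gene Rn18s-rs5, and left out clusters with over 75% of cells from 1 library at equal cell numbers. Where an alternative gives weighted values in place of sums, a gene's interval is the main one shifted to the new value, a rule also set after seeing the data.

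Free RNA was tested on the genes higher in every T class. The RNA added over the anti-IgG level was compared between the 2 single-cluster classes with the most cells, and a gene departed when its ratio of added RNA lay over 1.5 times from the median ratio in 97.5% of 1000 Poisson draws. This replaced a first test on Areg and Fosl2, which was void because Areg is not among those genes.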

Results

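Single-cell transcriptomes were measured in cells prepared from mouse hearts 7 days after myocardial infarction (MI, the death of heart muscle after its blood supply is blocked). One group of hearts came from mice injected with an antibody against PD1, the inhibitory receptor of T cells encoded by Pdcd1, and the other from mice injected with anti-IgG, the comparison group. Each group was 1 library, so no difference has a replicate check and no p-value is given. The intervals are 95% counting intervals, which leave out the variation between animals and preparations and, for gene ratios, between the cells of a library. The anti-IgG library held 4380 barcodes with 22806806 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), and the anti-PD1 library held 6026 barcodes with 29046341 UMIs. After filtering, 4160 anti-IgG and 5563 anti-PD1 cells were used, with medians of 4006.5 and 3779 UMIs per cell. T-lineage cells made up 88.8% of the anti-IgG and 87.8% of the anti-PD1 cells (3692 and 4884 cells). The rest were macrophage-like, dendritic-like, B-like, endothelial-like, fibroblast-like and cardiomyocyte-like cells and cells with markers of both T and B cells.

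The first comparison asked which kinds of T cells the hearts held under each antibody. Type 17 or gamma-delta T-like cells, which expressed Il17a and the Trdv4 and Trgv6 receptor segments, made up 8.15% (interval 7.29 to 9.08) of anti-IgG and 13.3% (12.3 to 14.3) of anti-PD1 T-lineage cells, a ratio of 1.63. CD8 T-like cells, which expressed Cd8a, Gzmk, Ccl5 and Eomes, made up 8.80% (7.91 to 9.76) against 12.04% (11.1 to 12.98). Their cluster 5 held 299 anti-IgG and 367 anti-PD1 cells, and their cluster 12 held 26 and 221, so this difference rested on cluster 12. NK-like cells, which carried Cd3 transcripts together with Klra7, Klrb1c and Ncr1, made up 4.71% (4.05 to 5.45) against 7.04% (6.34 to 7.80). CD4 T-like cells, which expressed Cd4 and Cd40lg, were a smaller share in the anti-PD1 library, at 18.1% (16.99 to 19.2) against 24.3% (22.9 to 25.7). CD8 naive or central memory T-like cells, with Dapl1 and Ccr7, were also a smaller share, at 10.1% (9.28 to 10.99) against 12.4% (11.3 to 13.5). With 1000 variable genes their ratio of shares was 0.974 (0.849 to 1.12), so this difference was then not beyond counting error.

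CD4 naive or central memory T-like cells had the same share in both libraries, 27.2% in each, but a ratio of shares of 1.20 (1.09 to 1.31) with genes centred within each library. Different clusters held them: cluster 0 gave 1020 of the anti-PD1 cells, and clusters 3 and 14 gave 661 and 182 of the anti-IgG cells. Treg-like cells, the regulatory T cells marked by Foxp3, made up 4.04% (3.42 to 4.72) of anti-IgG and 4.46% (3.90 to 5.08) of anti-PD1 T-lineage cells, and cycling-like cells 3.39% (2.83 to 4.02) and 3.21% (2.74 to 3.75). These differences lay within the counting intervals. Cluster 14 was led by the heat shock genes Hspa1b and Hspa1a. Cluster 8 of the CD4 T-like cells also held Foxp3 transcripts, in 22.4% of its cells, so the Treg-like class did not hold all Foxp3-bearing cells. Interferon-stimulated T-like cells (209 and 141 cells) were not compared in size, because the interferon genes that define them differed between the libraries. Unnamed T cells made up 1.33% (0.983 to 1.75) and 1.70% (1.36 to 2.10); they were cluster 19, led by Hspa1a and Hspa1b, and cluster 23, led by Hdac9, Myb and Sox4. The design text describes sorted T cells while the protocol records no sorting step, and any gate would set these shares.

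**Figure D1:**
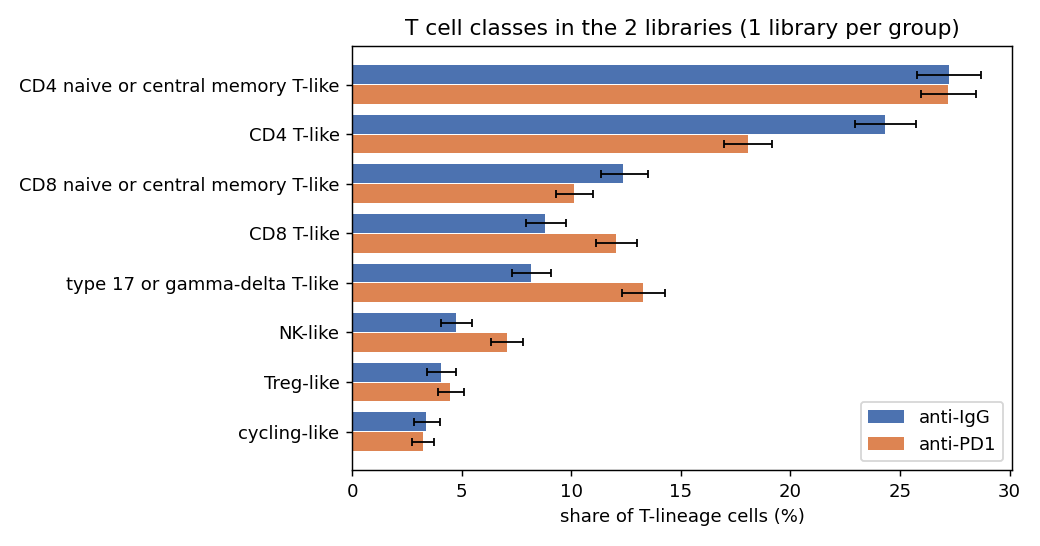
Share of T-lineage cells (percent, horizontal axis) in each named T cell class, for the anti-IgG and anti-PD1 libraries; bars are shares and error bars are exact 95% binomial intervals, which cover counting error only. The type 17 or gamma-delta T-like class stands at 8.15% and 13.3%, and the CD4 T-like class at 24.3% and 18.1%; interferon-stimulated and unnamed T cells are not drawn.

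The second comparison asked which genes differed in level over all T-lineage cells. Among the 12 genes with the highest ratios were the transcription factor genes Nr4a3, at 5.38 times the anti-IgG level (interval 5.03 to 5.77), Fosl2 at 5.18 times (4.83 to 5.57) and Atf3 at 7.62 times (5.80 to 10.2). Ptgs2, which encodes the prostaglandin-forming enzyme COX-2, had 10 anti-IgG and 228 anti-PD1 UMIs, a ratio of 18.4 (9.82 to 38.9). The class mix added to this ratio. At the same class mix Ptgs2 stood at 11.96, and within type 17 or gamma-delta T-like cells, a larger share of the anti-PD1 library, at 10.7. Vegfa, an angiogenic growth factor, stood at 6.91 times (3.96 to 13.02), Calca, the gene of the neuropeptide CGRP, at 6.23 times (4.42 to 9.03), and Ramp3, a partner of receptors for that peptide family, at 5.59 times (4.92 to 6.37). The others were Gprc5a (8.80), Sema4c (8.39), Trf (5.83), Muc1 (5.14) and Chrne (5.08). Lowest in the anti-PD1 library were the histone genes H2ac22 (0.168, interval 0.109 to 0.2503) and H3c3 (0.240, 0.191 to 0.298). Over the alternatives Ptgs2 ranged from 11.96 to 33.3 and Gprc5a from 5.04 to 14.8, and with cells thinned to 1000 UMIs Chrne stood at 11.1 and H2ac22 at 0.324.

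Also among the 12 lowest were the interferon-induced genes Ifit1bl1 (0.310, 0.264 to 0.364), Iigp1 (0.330, 0.269 to 0.402), Gvin1 (0.348), Gbp10 (0.361) and Slfn5 (0.399, 0.360 to 0.441). Lpar5 (0.359), AY036118 (0.366, with 3079 and 1399 UMIs), Pars2 (0.375), Adat1 (0.403) and Oxsm (0.403) completed the 12 lowest. When cells were thinned, the intervals of Gvin1 (0.718, 0.363 to 1.42) and Pars2 (0.698, 0.291 to 1.66) included 1. The median log2 ratio of all 11817 genes with at least 50 UMIs was -0.11, so a gene at a ratio of 1 stood slightly above the median gene. Of the transcript groups given only as sums, ribosomal RNA made up 5.398% of anti-IgG and 6.86% of anti-PD1 T-lineage UMIs, ribosomal protein genes 23.7% and 22.8%, mitochondrial genes 2.06% and 1.95%, and T cell receptor segments 0.252% and 0.241%.

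Pdcd1 itself, the target of the antibody, was 1.42 times as high in the anti-PD1 library (interval 1.35 to 1.496), from 2382 and 4201 UMIs. At the same class mix it was 1.22 times as high (1.16 to 1.29), so part of the difference came with the class mix. Other inhibitory receptors were higher as well: Tigit 1.68 times (1.57 to 1.79), Ctla4 1.49 times (1.42 to 1.56) and Havcr2 1.38 times (1.10 to 1.74). Cd274, which encodes PD-L1, a ligand of PD1, stood at 1.43 times (1.26 to 1.61). Lag3 did not differ beyond counting error (1.04, 0.818 to 1.33), and Tox stood at 1.22 (1.13 to 1.31). Among secreted factors, Areg, which encodes the growth factor amphiregulin, was 4.43 times as high (4.02 to 4.89), Il17a 1.96 times (1.85 to 2.07; 1.35 at the same class mix), Tgfb1 1.87 times (1.78 to 1.97) and Il10 1.71 times (1.04 to 2.87, from 25 and 53 UMIs; thinned 3.53, 0.985 to 19.1). Ifng (0.994, 0.916 to 1.08) and Tnf (1.01, 0.914 to 1.11) did not differ beyond counting error. Of the cytotoxic genes, Gzmb was 1.28 times (1.21 to 1.36) and Gzmk 1.16 times (1.08 to 1.25) as high, and Prf1 did not differ beyond counting error (1.05, 0.920 to 1.20). Lower in the anti-PD1 library were Cd4 (0.697, 0.662 to 0.733), Tcf7 (0.791, 0.768 to 0.814) and Mki67 (0.836, 0.788 to 0.886). Foxp3 (0.912, 0.841 to 0.990) and Cd8a (0.940, 0.899 to 0.983) lay below 1 but close to the median gene, whose log2 ratio was -0.11.

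**Figure D2:**
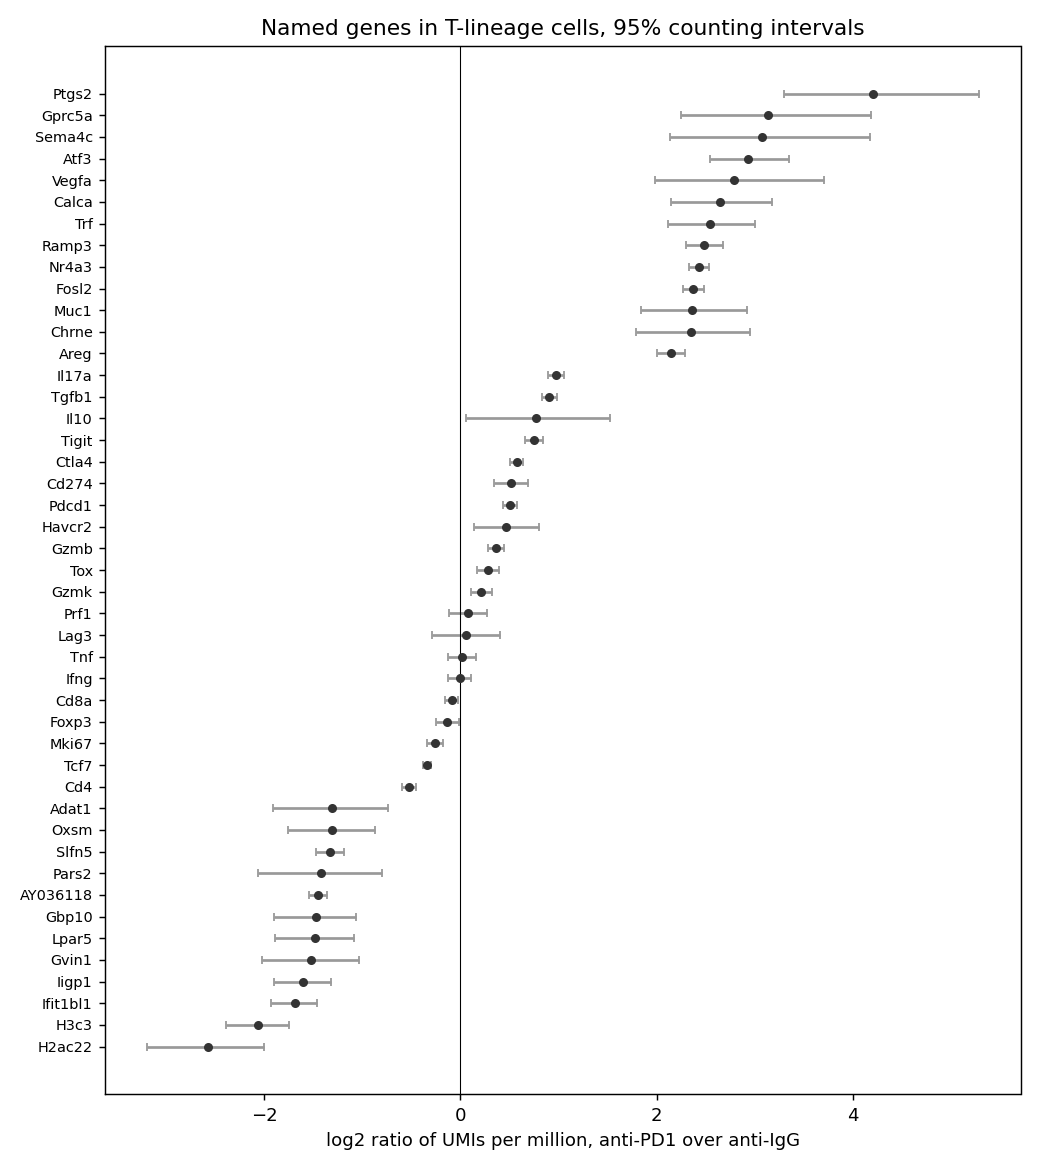
Log2 ratio of UMIs scaled to library totals (anti-PD1 over anti-IgG, horizontal axis) of the named genes in all T-lineage cells; points are ratios of summed UMIs and bars are 95% counting intervals. Ptgs2 lies at the top, with a ratio of 18.4, and H2ac22 at the bottom, with a ratio of 0.168.

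Shares of cells with a transcript were compared at fixed depth. With each T-lineage cell thinned to 1000 UMIs, which left out 49 anti-IgG and 66 anti-PD1 cells, Pdcd1 was seen in 9.17% (8.25 to 10.2) of anti-IgG and 12.3% (11.4 to 13.2) of anti-PD1 cells, and unthinned in 20.7% and 24.3%. In thinned B-like cells, as a measure of background, Pdcd1 was seen in 0 of 60 anti-IgG cells, which allows up to 5.96%, and in 0.645% of 155 anti-PD1 cells. Before thinning the median depths were 2771 and 2505 UMIs in B-like and 3915.5 and 3674.5 in T-lineage cells. The other genes named here, apart from Nr4a1, were seen in at most 1.67% of thinned B-like cells, and anti-IgG shares below 5.96% cannot be told from background with 60 B-like cells. Il17a was seen in 3.05% and 6.19% of thinned cells (4.90% and 9.36% unthinned). Areg was seen in 1.37% and 3.90% (2.95% and 8.15%), Gzmb in 3.51% and 6.19% (7.88% and 12.4%). Ctla4 was seen in 9.44% and 12.8% (20.5% and 27.3%) and Tigit in 6.12% and 10.4% (18.6% and 26.2%). Cd4 was seen in fewer anti-PD1 cells, 12.2% against 17.7% (30.1% against 43.0% unthinned). Foxp3 (3.82% and 3.57%; 6.96% and 6.31%) and Ifng (4.86% and 4.21%; 14.1% and 11.4%) had overlapping intervals after thinning. The interferon-induced Ifit3 was seen in 3.35% and 1.81% (8.37% and 4.63%), but Isg15 in 6.01% and 6.75% (14.8% and 17.2%) and Cd8a in 11.03% and 11.2% (22.4% and 23.5%), against their levels (0.916 and 0.940), so no order was read for either. Nr4a1 was seen in 8.13% and 29.9% (19.9% and 58.8%), and in B-like cells in 11.7% and 36.8%, so B-like cells give no background for it.

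The third comparison took gene lists fixed before the data were examined. In T-lineage cells all 40 measured members of the type I interferon response were lower in the anti-PD1 library, 26 of them to a ratio of 1/1.5 or less, with a median log2 ratio of -0.72 (percentile 0.0 among 10000 random lists matched on expression). Among them were Ifit1bl1, Phf11d (0.374, 0.205 to 0.659), Slfn5 and Ifi204 (0.431, 0.269 to 0.678). At the same class mix Phf11d stood at 0.585 (0.321 to 1.03) and Ifi204 at 0.712 (0.445 to 1.12), with intervals that included 1. Over the alternatives, the same class mix among them, the median of the type I interferon list ranged from -0.76 to -0.38 and stayed outside the random lists. The interferon gamma response and GTPases were lower in 24 of 31 members (median -0.33, percentile 0.0), with Ciita at 0.448 (0.263 to 0.746; thinned 0.504, 0.148 to 1.59) beside Iigp1 and Gbp10. The chemokine gene Cxcl10 was 2.499 times as high (2.15 to 2.91). Genes of naive and memory T cells were lower in 11 of 18 members (median -0.25, percentile 0.05). Slamf6 (0.556), Bcl2 (0.620) and Dapl1 (0.715) were lower and the lymph node homing receptor Ccr7 was higher (1.68, 1.63 to 1.73; 1.41 without clusters mostly of 1 library).

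The Th17 and gamma-delta 17 program was higher in T-lineage cells, with 14 of 15 members above a log2 ratio of 0 (median 0.54, percentile 100). Its median was 0.22 at the same class mix. Within type 17 or gamma-delta T-like cells, whose share was larger in the anti-PD1 library, it was 0.05 with 9 of 15 members above 0, inside the random lists (percentile 85.7). Il17f was 4.96 times (3.42 to 7.40), Il22 2.05 times (1.47 to 2.88; thinned 1.58, 0.763 to 3.44) and Rora 2.05 times (1.94 to 2.16) as high. Checkpoint and exhaustion genes were higher in 13 of 18 members (median 0.45, percentile 100), led by Nr4a2 (4.92, 4.47 to 5.42) and Nr4a1 (4.89, 4.65 to 5.14). Nr4a1 and Nr4a3 of this list were at least 1.5 times as high in every T class, and their rise was not particular to T cells. Nr4a1 stood at 4.44 (3.27 to 6.13) in the dendritic-like cluster led by Siglech. Nr4a3 stood at 9.32 (2.41 to 79.7) in macrophage-like cells without Cd3 UMIs. Cd200 was lower in T-lineage cells (0.474, 0.368 to 0.607). Early activation and AP-1 genes were higher in 18 of 26 (median 0.36, percentile 100), with Dusp4 at 3.37, Irf4 at 3.21 and Nfkbid at 2.96. NK receptors (15 of 17 higher, median 0.30, percentile 99.98; Klrc1 1.91, Cd244a 1.81) and cytotoxic effectors (14 of 19 higher, median 0.16, percentile 99.9; Ccl3 3.65, Ccl4 2.58, Gzma 2.04, Tnfsf10 0.610) were higher as found. With the same class mix in both libraries their medians were -0.03 and -0.03, with Klrc1 at 1.49 and Cd244a at 1.38, and without clusters mostly of 1 library the cytotoxic median (0.032) lay inside the random lists. The Treg program (14 of 24 higher, median 0.13, percentile 99.9) was led by Areg, Tnfrsf1b (3.44), Tnfrsf9 (1.97) and Tgfb1, and not by Foxp3. It lay inside the random lists when cells were thinned to 1000 UMIs (0.025) or clusters mostly of 1 library were left out (0.013). The unfolded protein response was higher in 13 of 16 (median 0.15, percentile 99.6; Dnajb9 2.06, Xbp1 1.76, Hspa5 1.38, Trib3 1.33 with an interval of 0.852 to 2.10, thinned 0.810), but lay inside the random lists with members of at least 200 UMIs (0.062). Heat shock and dissociation genes had a median of 0.11 (percentile 98.6) over members that went both ways, and lay inside the random lists with doublets kept (0.092) or cells thinned (0.091). Atf3 and Junb (1.76) were higher and the heat shock genes Hspa1a (0.566) and Hspa1b (0.569) lower; without clusters mostly of 1 library these stood at 0.764 and 0.699.

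**Figure D3:**
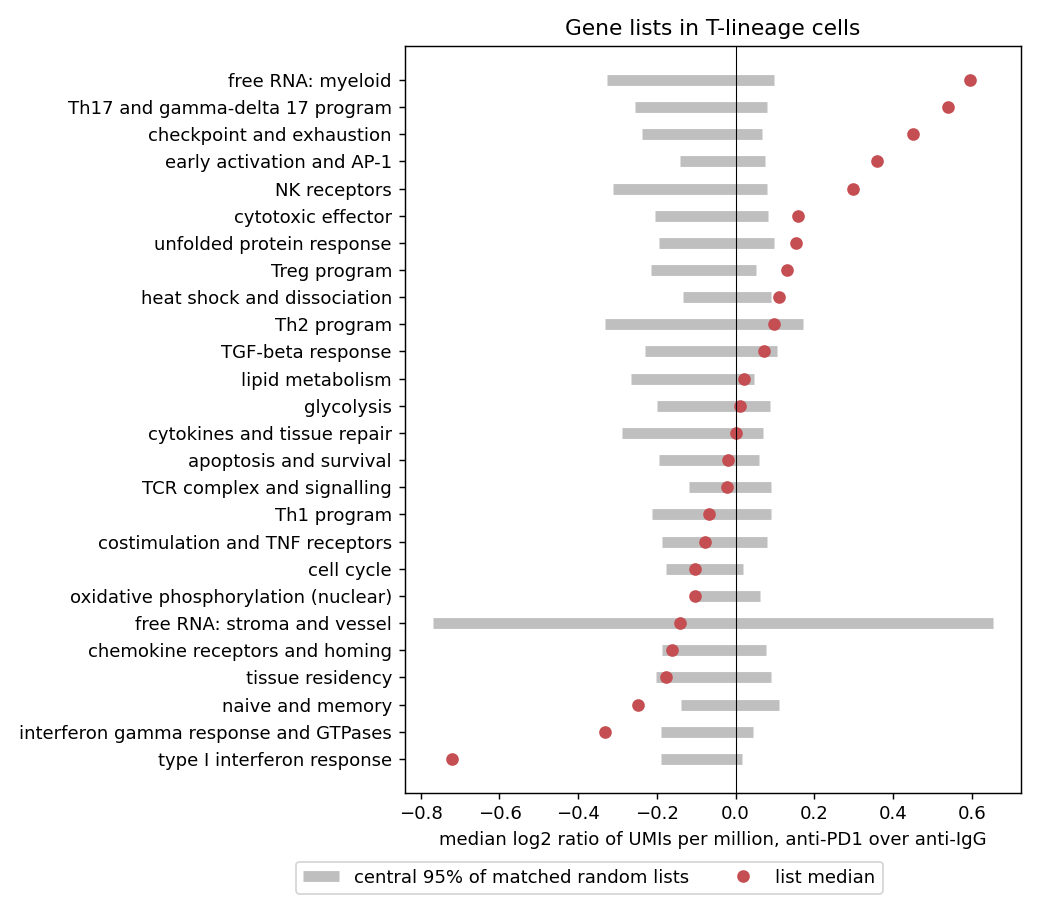
Median log2 ratio of UMIs scaled to library totals (anti-PD1 over anti-IgG, horizontal axis) of each fixed gene list in T-lineage cells; points are list medians and grey bars the central 95% of matched random lists. The type I interferon response lies lowest of those drawn, at -0.72, and the free RNA list of myeloid cells highest, at 0.60; the red cell list is not drawn.

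The other lists lay within the central 95% of random lists in T-lineage cells as found. Among them were the Th1 program (median -0.07; Il2 0.460, Cxcr3 0.556, Il12rb2 1.74, Stat4 1.28), the Th2 program (0.10; Il4ra 1.82, Maf 0.719, Il4 0.629 with an interval of 0.384 to 1.02) and cell cycle (-0.10; Cks2 1.61, Cenpa 1.54, Cenpe 0.627, Cenpf 0.664). Others were chemokine receptors and homing (-0.16; Cxcr4 1.98, Ccr9 0.452), tissue residency (-0.18; Crem 4.28, Bhlhe40 3.13, Rgs2 2.38, Xcl1 2.18) and cytokines and tissue repair (0.0015; Vegfa, Areg, Il2 and Il22 above). They further included costimulation and TNF receptors (-0.08; Tnfsf11 2.37, Icos 2.03), TCR complex and signalling (-0.02; Cblb 1.58, Malt1 1.35, Themis 0.669) and glycolysis (0.01; Hk2 3.99, Slc16a3 1.67, Slc2a1 1.34, Eno1 0.741). Oxidative phosphorylation (-0.10; Atp5k 0.623, Atp5l 0.686, Ndufa3 0.709, Ndufs5 0.742) and lipid metabolism (0.02; Sqle 1.58, Fabp5 1.44, Srebf1 0.740, Cpt2 0.588) also lay within that range. So did apoptosis and survival (-0.02; Cdkn1a 5.08, Gadd45b 2.71, Bcl2a1d 2.07, Tnfrsf10b 1.98) and TGF-beta response (0.07; Tgif1 2.79, Skil 2.13, Pmepa1 1.86, Smad7 1.35). Some of these medians lay outside the random lists under an alternative. At the same class mix these were tissue residency (-0.27), chemokine receptors and homing (-0.25) and TGF-beta response (0.10). Without clusters mostly of 1 library they were cytokines and tissue repair (0.29), costimulation (0.093), lipid metabolism (0.11) and oxidative phosphorylation (-0.10). Oxidative phosphorylation also lay outside with doublets kept (-0.11) or at least 1000 genes per cell (-0.10), and cytokines and tissue repair with each cell weighted alike (0.085). Among the members of these lists, the intervals of Cenpe (0.779), Cpt2 (0.725) and Sqle (1.95) included 1 when cells were thinned, and Hk2 stood at 10.6. Without clusters mostly of 1 library Il4 stood at 1.13, Cks2 at 1.39, Cenpa at 1.37 and Cblb at 1.41. Transcripts of other cells also differed within T-lineage cells. Myeloid transcripts were higher in 12 of 16 members (median 0.60, percentile 100; Arg1 2.86, Tyrobp 2.00, Fcer1g 1.80, H2-Eb1 1.72), and Tyrobp and Fcer1g are also NK cell genes. Arg1 stood at 1.32 (0.336 to 6.16) and H2-Eb1 at 3.53 when cells were thinned, and Tyrobp at 1.45 and Fcer1g at 1.33 at the same class mix. Red cell transcripts were nearly confined to the anti-IgG library (median -8.35; Hbb-bs 670 and 1 UMIs, Hba-a1 525 and 3, Hba-a2 398 and 1, Hbb-bt 116 and 0), where Hbb-bs was seen in 0.163% of T-lineage cells. Stroma and vessel transcripts had a median of -0.14 over 3 measured members (Pecam1 0.845; Sparc 0.907, from 0.570 to 1.36 over the alternatives; Fabp4 1.05), and under 3 heart muscle transcripts reached 50 UMIs, so that list gave no median.

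The fourth comparison asked which differences were present within each T cell class. The type I interferon list was lower in the anti-PD1 library in CD4 naive (median -0.67), Treg-like (-0.65), type 17 or gamma-delta T-like (-0.60), CD8 T-like (-0.48), cycling-like (-0.44), CD8 naive (-0.43), CD4 T-like (-0.36) and interferon-stimulated (-0.28) cells, each below the central 95% of random lists; in NK-like cells (-0.22) it lay just inside. It also lay inside in CD4 T-like cells without clusters mostly of 1 library (-0.22), in CD8 T-like cells when thinned (-0.21), in CD8 naive cells with members of at least 10 UMIs (-0.23), and in interferon-stimulated cells when thinned (-0.11) or with at least 1000 genes per cell (-0.091). Early activation and AP-1 genes were higher in cycling-like (0.75), type 17 or gamma-delta T-like (0.66), CD8 T-like (0.52), NK-like (0.46), CD4 T-like (0.41), interferon-stimulated (0.39), Treg-like (0.24) and CD8 naive (0.16) cells, but not in CD4 naive cells (-0.11). In CD8 naive cells they lay inside the random lists with doublets kept (0.13) or at most 5% mitochondrial UMIs (0.13). Checkpoint and exhaustion genes had their highest medians in type 17 or gamma-delta T-like (1.05), NK-like (0.76) and cycling-like (0.74) cells and a median of -0.02 in Treg-like cells. Across the 9 classes, 79 genes measured in at least 6 of them were at least 1.5 times as high in each class measured, among them Nr4a3 (3.46 to 7.30), Fosl2 (3.74 to 8.84), Crem (2.82 to 6.34) and Ramp3 (3.46 to 10.5). In turn 16 genes were lower to 1/1.5 or less, among them Txnip (0.303 to 0.562) and Ifi213 (0.376 to 0.582). These genes were collected after the values were seen. The 79 genes were also higher in B-like cells (median log2 ratio 0.81) and in the dendritic-like cluster led by Siglech (0.74). The type I interferon list stood at -0.69 and -0.71 there. These medians took members with at least 10 UMIs.

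**Figure D4:**
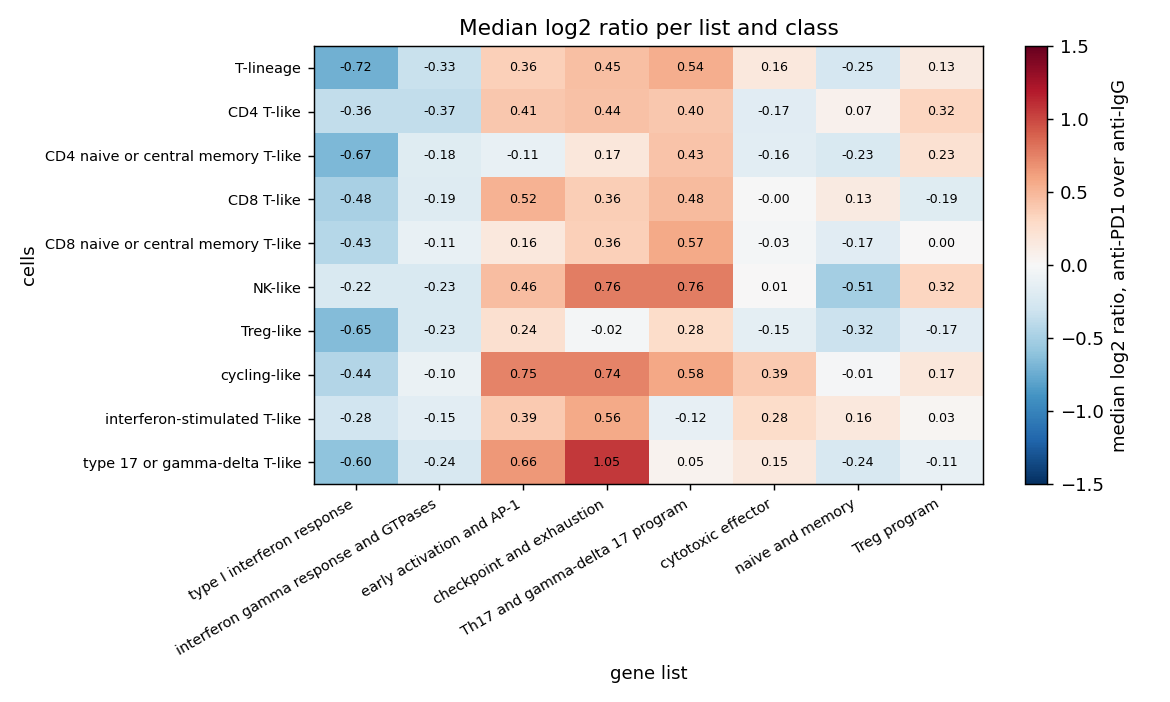
Median log2 ratio (anti-PD1 over anti-IgG; colour and printed value) of 8 fixed gene lists (columns) in T-lineage cells and in each T cell class (rows). The type I interferon column is negative in each row where it lies outside the random lists, from -0.72 in T-lineage cells to -0.28 in interferon-stimulated cells.

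Within type 17 or gamma-delta T-like cells the 5 highest genes were Il22 (3 and 103 UMIs, ratio 17.5, interval 5.81 to 86.1), Ptgs2 (10.7, 5.70 to 22.6), Calca (10.2), Muc1 (8.06) and Nr4a3 (6.99). Areg was 5.07 times (3.93 to 6.65), Ctla4 2.65 times (2.12 to 3.35), Tgfb1 2.15 times (1.87 to 2.49), Il17a, one of the genes that define the class, 1.30 times (1.22 to 1.38) and Pdcd1 1.26 times (1.16 to 1.36) as high. The lowest were Txnip (0.303, 0.266 to 0.344), Ifi27l2a (0.360), Pik3ip1 (0.368), Bmt2 (0.378) and Nxpe3 (0.411). In thinned cells Il22 stood at 9.27 and Ptgs2 at 19.5, and the intervals of Ifi27l2a (0.564) and Nxpe3 (0.551) included 1; Calca stood at 17.2 with each cell weighted alike, and Ifi27l2a at 0.635 with doublets kept.

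CD4 T-like cells of the anti-IgG library lay mostly in cluster 4 (584 of 898 cells), which was led by Cxcr3, Zfp683 and Cd40lg. Those of the anti-PD1 library had their largest part in cluster 7 (383 of 882 cells), led by Tnfsf11, Ramp3 and Ccr4, with 222 cells in cluster 4. Cluster 8 held 200 anti-IgG and 277 anti-PD1 cells. Highest in this class were Cxcl2 (2 and 149 UMIs, ratio 87.6, interval 23.8 to 730), Atf3 (25.5), Areg (17.2, 11.6 to 26.4), Cdkn1a (10.9) and Ramp3 (8.85). Lowest were Ccl1 (0.0823, 0.0323 to 0.176), H2ac20 (0.312), Ifit1bl1 (0.333), Zfp426 (0.367) and Hspa1a (0.367). Hspa1a was higher when doublets were kept (1.24) or with at most 5% mitochondrial UMIs (1.25). With at least 1000 genes per cell it did not differ beyond counting error (1.10, 0.952 to 1.27). Ctla4 was 2.32 times (2.12 to 2.54; 1.42 without clusters mostly of 1 library) and Pdcd1 1.36 times (1.20 to 1.53) as high. Over the alternatives Cxcl2 ranged down to 42.9, Atf3 from 13.7 to 42.2, Areg down to 8.66, Ramp3 down to 4.98, Ccl1 from 0.0360 to 0.286 and Ifit1bl1 down to 0.142, and H2ac20 when thinned (0.713, 0.269 to 1.80) did not differ beyond counting error. The Th2 program had a median of 0.77 and the Th1 program -0.30. The Th1 median lay inside the random lists with doublets kept (-0.24), at least 1000 genes per cell (-0.25), cells weighted alike (-0.23) or thinned (-0.26). Without clusters mostly of 1 library, the Th2 median was 0.20 and inside the random lists, the Th1 median was 0.17, the Th17 median -0.09 (0.40 as found) and the Treg program -0.14 (0.32 as found), so the direction of the last 3 medians depended on those clusters. The medians of tissue residency and of cytokines and tissue repair turned as well, from -0.32 to 0.64 and from -0.44 to 0.04.

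CD8 T-like cells, whose cluster 12 held 26 anti-IgG and 221 anti-PD1 cells, had Nr4a1 (7.80, 6.39 to 9.60), Cdkn1a (6.55), Ramp3 (6.05), Tubb2a (5.90) and Nr4a3 (5.76) as the highest genes. Lowest were Irf2bp2 (0.305), AI467606 (0.308), Ifit1bl1 (0.312), BE692007 (0.386) and Slfn8 (0.387). With thinned cells Nr4a1 stood at 5.02 and AI467606 at 0.464, and the intervals of Ramp3 (2.54), Tubb2a (2.996) and Ifit1bl1 (0.508) included 1, as did that of Ramp3 without clusters mostly of 1 library (4.73). Gzmb was 1.84 times (1.65 to 2.05) as high and Ifng lower (0.776, 0.658 to 0.917). In NK-like cells Rgs16 (10.3, 5.50 to 21.9), Cdkn1a (7.94), Tnfrsf9 (7.70), Rrad (7.68) and Nr4a1 (7.65) were highest. Gzmb was 1.85 times (1.51 to 2.27; 1.46 with doublets kept) and Tigit 2.78 times (2.19 to 3.56) as high. AY036118 (0.294), Pik3ip1 (0.296), Txnip (0.306), Slamf6 (0.321) and Tia1 (0.385) were lowest. Some of these moved: Rgs16 to 15.7 with at most 5% mitochondrial UMIs, Cdkn1a to 12.5 with doublets kept, and in thinned cells Tnfrsf9 to 12.1, Rrad to 11.6, AY036118 to 0.446 and Tia1 to 0.413, whose interval (0.151 to 1.095) included 1. Cycling-like cells had Areg (6 and 222 UMIs, 31.9, interval 14.4 to 87.9), Rgs16 (9.68), Fosl2 (8.84), Ier5l (8.19) and Nr4a1 (7.53) at the top. At the bottom were Gzmc (0.0421, 0.0151 to 0.0942), H2ac22 (0.151), H3c3 (0.252), Trat1 (0.342) and P2rx7 (0.345). After thinning Areg stood at 12.99 and P2rx7 at 0.125, and the intervals of Rgs16 (4.87), H2ac22 (0.406) and Trat1 (0.541) included 1; Gzmc stood at 0.104 with each cell weighted alike.

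In Treg-like cells Areg was 2.49 times as high (2.22 to 2.81), while Gzmb was lower (0.468, 0.407 to 0.538); Ctla4 (1.01, 0.945 to 1.09) and Pdcd1 (0.932, 0.820 to 1.06) did not differ beyond counting error. Their 5 highest genes were Ramp3 (8.15, 4.72 to 15.2), Xcl1 (8.02), Trf (6.36), Vps37b (5.27) and Prr7 (4.32), and the lowest were Hspa1a (0.180), Penk (0.355, 0.3001 to 0.419), Trim59 (0.358), Kcnq1ot1 (0.368) and Txnip (0.374). When Treg cells were taken by Cd3 and Foxp3 UMIs in place of clusters, Xcl1 stood at 0.994, Trf at 1.12, Hspa1a at 0.620, Penk at 1.27 and Gzmb at 0.677. With each cell weighted alike Xcl1 stood at 14.7 and Trim59 at 0.614. When thinned, Prr7 stood at 2.64 and Hspa1a at 0.0476, and the intervals of Trf (4.14) and Trim59 (0.376) included 1.

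Naive cells of both lineages shared 3 of their 5 highest genes: Tnfrsf1b (5.65 in CD4 and 7.03 in CD8 naive cells), Fosl2 (5.13 and 5.85) and Crem (4.27 and 4.81). CD4 naive cells also had Nr4a2 (4.80; thinned 34.1) and Ramp3 (4.55) among the highest. Their lowest were Cd200 (0.295), AY036118 (0.341), Ifi206 (0.356), Ddit4 (0.357) and Hspa1a (0.358). All CD4 naive cells lay in clusters mostly of 1 library. One of these was cluster 14, led by Hspa1b and Hspa1a, with 182 anti-IgG and 45 anti-PD1 cells. CD8 naive cells, a single cluster with 457 and 494 cells, also had Tubb2a (5.49) and Nr4a3 (4.54) among the highest. Their lowest were Hspa1b (0.148, 0.117 to 0.187), Hspa1a (0.159), Ifi206 (0.339; thinned 0.554, 0.247 to 1.19), AY036118 (0.342) and Gvin-ps6 (0.352). Interferon-stimulated T-like cells had Serpinb6b (7.77), Bhlhe40 (6.82), Nr4a1 (6.58), Nr4a3 (5.91) and Fosl2 (5.70) as the highest. Their lowest were Hspa1a (0.368), Zranb2 (0.384), Dennd2d (0.389), AY036118 (0.396) and Zfp148 (0.410). Of these, Serpinb6b stood at 14.7 and Hspa1a at 0.113 in thinned cells, where the intervals of Zranb2 (0.392), AY036118 (0.817) and Zfp148 (0.490) included 1, and Dennd2d stood at 0.187 with at least 1000 genes per cell.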

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

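Shares of cells outside the T lineage were not compared between the libraries in the report. B-like cells made up 2.80% (interval 2.39 to 3.27) of the anti-PD1 cells against 1.44% (1.10 to 1.85) of the anti-IgG cells. Cells with markers of both T and B cells made up 1.85% (1.51 to 2.24) of the anti-PD1 and 0.865% (0.607 to 1.20) of the anti-IgG cells, with a median of 7365 UMIs per cell in the anti-PD1 library against 3674.5 in T-lineage cells. Both stood above the level in the comparison library. Endothelial-like cells went the other way, at 0.773% (0.560 to 1.04) of the anti-PD1 and 1.97% (1.57 to 2.44) of the anti-IgG cells. The other classes outside the T lineage had overlapping intervals.

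Levels of granzyme genes differed in opposite directions between classes, and the difference between classes was not tested. Shares of Treg-like cells with a UMI were not lower in the anti-PD1 library: 31.5% of anti-IgG and 33.0% of anti-PD1 cells for Gzmb, 5.37% and 5.96% for Gzmk. In interferon-stimulated cells Gzmb was seen in 9.09% of 209 and 16.3% of 141 cells, and in cycling-like cells Gzmk in 35.2% and 38.2%. Gzmb was 3.87 times as high (2.96 to 5.10) in interferon-stimulated T-like cells and lower in Treg-like cells (0.468, 0.407 to 0.538), a log2 difference of 3.05. Gzmk was 2.05 times as high (1.70 to 2.49) in cycling-like cells and lower in Treg-like cells (0.515, 0.310 to 0.848, from 40 and 30 UMIs), a log2 difference of 2.00. In Treg cells taken by marker UMIs, Gzmb stood at 0.677 (0.599 to 0.765) and Gzmk at 1.12 (0.837 to 1.498), so the opposite direction of Gzmk was not kept there. The Gzmk interval in Treg-like cells also included 1 with each cell weighted alike (0.965, 0.580 to 1.59), with at least 1000 genes per cell (0.699, 0.443 to 1.10) and thinned to 1000 UMIs (0.690, 0.0500 to 9.52), and in cycling-like cells when thinned (1.14, 0.641 to 2.07). With 1 library per group no sample could be compared with others of its group.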

How the results depend on the processing

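Leaving out clusters mostly of 1 library, Trdv4 or Trgv6 gating and scaling without Rn18s-rs5 were chosen only after the results were seen. Over the alternatives, 332 medians of lists in T-lineage cells kept their place inside or outside the random lists, though 24 of these, all inside, changed sign; 10 came to lie outside, 1 of them with another sign, 6 ceased to, and 2 that lay outside changed sign; the type I interferon median ranged from -0.76 to -0.38. Of the ratios of shares 86 stayed within the counting interval. Of the gene ratios 3623 kept their side of the size and interval limits (121 of them turned direction), 106 no longer passed (69 with intervals that included 1), 82 came to pass, 11 of them in the other direction, and 11 that had passed turned direction. Of the list medians that lay outside the random lists within classes, 894 stayed outside with the same sign, 192 came to lie inside with the same sign, and 29 changed sign, 24 of them then inside. The Pdcd1 ratio ranged from 1.22 to 1.53, the last when scaled by the median ratio, and the type 17 or gamma-delta ratio of shares from 1.49 to 1.69. Unthinned, the ratio of shares of cells with a UMI moved for Tigit (1.40) and Nr4a1 (2.96). Marker UMIs gave no value for classes other than Treg and CD4 or CD8 cells, the same class mix none within a class. Leaving out clusters mostly of 1 library removed 43.9% of anti-IgG and 37.0% of anti-PD1 T-lineage cells, among them all CD4 naive cells, 65.0% and 25.2% of CD4 T-like and 8.0% and 37.6% of CD8 T-like cells, so it gave no value within CD4 naive cells; the other named classes lost no cell and were not counted for it. The depth of the small classes limits rare genes. No paired analysis was possible because each group is 1 library. The causes of the changes below were not tested.

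With doublets kept, the ratio of shares of NK-like cells was 1.87, and medians were 0.092 for heat shock (then inside the random lists) and -0.11 for oxidative phosphorylation (then outside) in T-lineage cells, -0.14 for naive and memory in CD8 T-like cells, and 0.056 for tissue residency in CD4 T-like cells, where Hspa1a stood at 1.24. With at least 1000 genes per cell, the share ratio of all CD4 cells was 0.823 (0.878 as found) and oxidative phosphorylation was -0.10 and outside. Naive and memory was then -0.00018 in CD8 T-like and -0.0056 in interferon-stimulated cells, and Hspa1a was 1.10 in CD4 T-like cells. Cd8a in Treg-like cells was then 1.06 (0.742 to 1.53), against 0.466 as found. With at most 5% mitochondrial UMIs, CD4 T-like cells had 0.10 for tissue residency and 1.25 for Hspa1a. From marker UMIs, the share ratio of all CD4 cells was 0.704, and in Treg cells Gzmk stood at 1.12, Penk at 1.27 and Xcl1 at 0.994. With 1000 variable genes the share ratio of CD8 naive cells was 0.974. With centred genes the share ratio was 1.20 for CD4 naive cells and 0.989 (0.928 to 1.05) for all CD4 cells, the last then not beyond counting error.

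Thinned to 1000 UMIs, T-lineage medians were 0.025 for the Treg program and 0.091 for heat shock, both then inside the random lists. Medians within classes, all then inside the random lists and of the other sign than as found, were -0.54 for NK receptors and 0.025 for interferon gamma in Treg-like cells. Cell cycle in NK-like cells was -0.24 in the same way. Others were -0.082 for lipid metabolism and -0.039 for unfolded protein response in CD4 naive cells, -0.017 for naive and memory in interferon-stimulated cells, 0.037 for oxidative phosphorylation in cycling-like cells, and for tissue residency 0.022 in CD4 T-like and -0.014 in type 17 or gamma-delta cells. In cycling-like cells thinned ratios were 0.974 (0.248 to 4.03) for Cd274 and 0.812 (0.0103 to 63.7) for Havcr2, against 1.84 and 3.74 as found. Mki67 in Treg-like cells stood at 1.10 (0.318 to 4.29) thinned, against 0.501 as found. Tnf in NK-like cells stood at 0.757 (0.179 to 3.65) thinned, against 2.30 as found. All of these thinned intervals included 1. With each cell weighted alike, Th17 in Treg-like cells was -0.072 and cytokines and tissue repair in T-lineage cells 0.085, then outside.

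With members of at least 10 UMIs, type 17 or gamma-delta cells had -0.050 for apoptosis, -0.16 for cytokines and tissue repair and -0.076 for cytotoxic effectors. The cytokine list was then 0.25 in CD4 naive and 0.39 in CD8 naive cells, and lipid metabolism in CD4 naive cells -0.10. With at least 200 UMIs, myeloid transcripts were -0.020 in CD4 naive and -0.022 in cycling-like cells and the unfolded protein response 0.062 in T-lineage cells. At the same class mix, T-lineage medians were -0.030 for NK receptors, -0.028 for cytotoxic effectors, and, then outside the random lists, 0.10 for TGF-beta response, -0.25 for chemokine receptors and -0.27 for tissue residency. Without clusters mostly of 1 library they were 0.013 for the Treg program and 0.032 for cytotoxic effectors, both then inside the random lists. Then outside were 0.093 for costimulation (-0.08 as found), 0.29 for cytokines and tissue repair, 0.11 for lipid metabolism and -0.10 for oxidative phosphorylation. CD4 T-like cells then had 0.17 for Th1, -0.086 for Th17, -0.14 for the Treg program, 0.035 for cytokines and tissue repair and 0.64 for tissue residency, and CD8 T-like cells -0.37 for naive and memory.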

Other observations

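The tests of a cluster mix, of free RNA, of the CD4 T-like share, of differences between animals, of the class mix for Pdcd1 and of both hypotheses on CD8 naive cells were chosen only after the results were seen. The genes in the next paragraph were chosen after their values were seen.

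In macrophage-like cells without a Cd3 UMI (49 anti-IgG and 117 anti-PD1 cells), Ptgs2 had 3 and 187 UMIs (ratio 29.8, interval 10.0 to 146) and was seen in 18 anti-PD1 cells, Cxcl1 had 4 and 202 UMIs (24.1, 9.28 to 89.4), and Tnfsf9 had 4 and 158 (18.9, 7.23 to 70.2). Saa3 (6 and 458 UMIs) and Retnla (0 and 154) came from 3 and 4 anti-PD1 cells, so these 2 values rest on few cells. The monocyte gene Ly6c2 was lower (0.225, 0.164 to 0.305), from 8 cells in each library. Cluster 23, which was led by Hdac9, Myb, Sox4 and Rag1, genes of developing lymphocytes, held 6 anti-IgG and 36 anti-PD1 cells.

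Genes higher in every T class and the lower type I interferon list were weighed as shifts of the whole library. The 79 genes higher in every T class had a median log2 ratio of 1.42 over the classes, and also 0.81 (0.63 to 1.02) in B-like cells and 0.74 (0.56 to 0.85) in the dendritic-like cluster led by Siglech; the interferon list stood at -0.69 (-0.86 to -0.22) and -0.71 (-0.86 to -0.37) there. These medians were each above 0.5 of the one in T cells, with intervals that reached lower for all but the dendritic-like interferon value. Preparation or handling that differed between the libraries could give them, and so could an effect of the antibody on many cell types. The medians in these cells took members with at least 10 UMIs, while the T-lineage interferon median of -0.72 took members with at least 50. At 10 UMIs the interferon list ran from -0.73 in Treg-like to -0.23 in CD8 naive cells. In macrophage-like cells without Cd3 UMIs 73 of the 79 genes were measured and stood at 0.83 (0.65 to 1.02). There 12 of the 16 genes lower in every T class stood at -1.10 (-1.53 to -0.83). The interferon list stood there at -0.24 (-0.42 to -0.041), short of 0.5 of the T-lineage median. The tables argue against a mix of clusters as the whole cause, since genes chosen on the other classes had a median of 1.04 (0.94 to 1.10) in CD8 naive cells, a single cluster. Free RNA from 1 source stays open, since 17 of 73 genes (23.3%) departed from 1 ratio of added RNA between CD8 naive and type 17 or gamma-delta cells, between the 10% and 50% set as limits, and so do treatment and handling, because each group is 1 library.

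The higher share of type 17 or gamma-delta T-like cells did not come from cluster boundaries alone: cells with a Trdv4 or Trgv6 UMI, segments not used for clustering and whose detection depends on which transcript end was read, had a ratio of shares of 1.49 (1.29 to 1.72). Nor did it follow from fewer CD4 T-like cells, as the ratio was 1.503 (1.31 to 1.73) over the other T-lineage cells. That ratio is a recalculation from the same cell counts as the shares and not a separate test. Differences between animals or hearts unrelated to the treatment cannot be told apart from the treatment with 1 library per group. The ratio of Pdcd1 was 1.22 (1.16 to 1.29) at the same class mix, against 1.42 as found, so a different mix of classes was not the whole of it.

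A hypothesis is that the genes higher in CD8 naive cells may reflect a response of cAMP and CREB type, and a second is that they may reflect antigen-receptor stimulation. Both lists were written after other values in these cells were known, and members of both, among them Rgs2, Irf4 and Nfkbid, had been seen to be higher, so neither test is independent. Per1, Sik1, Nfil3, Rgs2 and Cebpb of the first list and Nfkbid of the second are among the 79 genes higher in every T class. Those 79 genes were also higher in B-like (0.81), dendritic-like (0.74) and macrophage-like cells without Cd3 UMIs (0.83), so neither test is particular to CD8 naive cells. A list of CREB target genes had a median of 0.49 with 11 of 12 members above 0 (percentile 100), led by Nfil3 (4.75), Per1 (2.88) and Sik1 (2.18), with Pde3b lower (0.726). A list of receptor-induced genes had a median of 0.28 with 6 of 10 above 0 (percentile 98.9), with Irf4 at 4.60 and Nfkbid at 2.17 but Cd69 at 0.652 and Cd5 at 0.730. Both lists passed the limit set for them, so the tests do not separate the 2 hypotheses.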
